A study of Mus musculus with 18 samples.

How the data were processed

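Accessible chromatin was measured in 18 ATAC-seq libraries, 2 for each of 9 treatments, per the labels. Macrophages were grown from C57BL/6 bone marrow with M-CSF (20 ng/mL) and replated on day 7, and nuclei were treated with transposase for 30 minutes at 37 °C, per the labels' protocols. The tools used before deposit were Bowtie2 2.2.5, SAMtools 1.9, Picard, MACS3 3.0.0b1 and featureCounts, with the genome build mm10 (GRCm38), per the submitters' processing notes, which as given here list the tools without their settings. The deposited file holds log2 CPM per region and library. How the regions were merged across libraries is not stated there.

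The log2 values were made by the authors from reads per region before they were deposited, and the deposited values themselves show how. All values of each library (100%) return whole reads within 0.01 when a mean prior of 3 reads and effective library sizes of 3196806 to 5982866 are assumed, with 0 reads at a log2 value of -0.70. The prior pulls regions with few reads toward each other, so log2 differences at low regions are understated. Reads in regions ranged from 3141641 to 5986835 per library, with medians of 40 reads per region in MM replicate 2 to 75 in CT replicate 2. The median SE of a log2 difference between 2 groups was 0.205, and 0.29 for a difference of differences.

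The 53796 regions, each spanning 501 bases from start to end on 20 chromosomes, were used without a filter, with coordinates as deposited. The reference held positions of 21900 protein-coding genes without strand, so a region was assigned to the protein-coding gene whose body was nearest within 50 kb, and places are given relative to a gene end rather than a start. This assigned 48831 regions to 13767 genes. Assignment does not show which gene a region regulates. A genome sequence was not used here, so the planned motif tests and their alternatives were not run.

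Limma 3.58.1 in R 4.3.3 fitted the 9 group means to the deposited log2 values, with empirical Bayes variances following a trend on mean level (9 residual and 29.09 prior degrees of freedom). The 12 contrasts were each stimulus alone against medium, each first stimulus against medium under the same second stimulus, CpG against polyI:C as first stimulus, and the interactions of first and second stimulus. P-values were adjusted over all regions by Benjamini and Hochberg, and regions under 0.05 were called. Per contrast, 16 gene lists with 436 genes, of which 433 were in the reference and 378 had a region, were tested with camera at a preset correlation of 0.01. The lists were inflammatory cytokines and effectors, NF-kB subunits and negative feedback, interferon-stimulated genes, AP-1 and immediate early factors, macrophage identity, cholesterol and lipid handling, alternative activation, antigen presentation and costimulation, receptors and signalling of TLR and TNF pathways, cell cycle, and markers of T and NK cells, B cells, neutrophils, dendritic cells, erythroid cells and progenitors, and fibroblasts, stroma and endothelium. Camera p-values were adjusted over the lists of a contrast. Each list was also tested with the correlation between its regions estimated, and its regions were adjusted over the list alone. Regions called with a single stimulus were tested as sets in the comparisons with 2 stimuli in the same way. Comparisons that share control libraries were set against 100 simulations of unchanged groups.

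The groups, contrasts, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Named regions are, per contrast, the 6 largest rises and 6 largest falls among called regions in which both libraries of one group lay above both of the other and the higher mean was at least 1. To these were added up to 4 called regions per list with the smallest p, and 1 region for each of Tnf, Il1b, Il6, Il12b, Cxcl10, Ifit1, Nfkbia, Tnfaip3, Socs3 and Csf1r, with 1 region per gene. Predicted genes and unnamed transcripts were skipped, and the text names some of the regions that met this rule. Ifit1 had no region. The labels give replicate numbers but not their origin, and no pairing between groups was established, so no block was used.

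The fit was tested on simulated reads with a dispersion of 0.01 and 200 regions changed per comparison. In the MC against MM simulation, 4%, 68%, 98% and 100% of log2 changes of 0.5, 1, 2 and 3 were recovered among 53796 regions, with 5 other regions called. In the simulated CpG interaction these shares were 0%, 22%, 92% and 100%, with 1 other region called. The alternatives changed 1 choice at a time. They were quantile normalization, libraries shifted to one median, only regions at or above the 25th percentile of mean level (40347 regions), log2(CPM + 1), no variance trend, robust variances, only the compared groups in the fit, the replicate number as a block, and each library left out. Voom on recovered reads, assignment by the nearest gene end, list tests with each library left out, the MP libraries averaged to 1 sample, and 4 contrasts given in the closing section were chosen after seeing the data. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.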

Results

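Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts adapters into open DNA, in bone marrow-derived macrophages from wild-type C57BL/6 mice. The cells received a first stimulus or medium for 4 h and then a second stimulus or medium for 4 h. The stimuli were CpG (100 nM), a DNA ligand of an endosomal Toll-like receptor, LPS (1 ng/mL), a bacterial cell wall component, polyI:C (1 µg/mL), a double-stranded RNA mimic, and the cytokine TNF (10 ng/mL). The 9 groups are written by their first and second treatment, with M for medium, C for CpG, L for LPS, P for polyI:C and T for TNF. They were MM, MC, ML, MP, MT, CL, PL, CT and PT, with 2 libraries each. Values were log2 CPM, reads of a region scaled to the size of the library, at 53796 regions. Of these, 12143 lay within 1 kb of a gene end, 24053 inside a gene, 12635 between genes and 4965 over 50 kb from a gene. Reads in the regions ranged from 3141641 in MM replicate 2 to 5986835 in MT replicate 1, with a median of 4962629. Replicates correlated across regions at 0.919 in PT and at 0.958 to 0.973 in the other groups. Differences are log2 CPM ± SE with n = 2 libraries in each group, called at a limma adjusted p under 0.05. The labels name no separate animals or cultures for the replicates, so these p-values measure only the spread between these libraries. That spread was estimated for each region over all 9 groups together. The PT replicates differed more than the others, so the SE and p-values may understate the spread in comparisons with PT.

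CpG alone was compared with medium to measure the response to this stimulus. The largest rise in MC lay near Fpr1, a formyl peptide receptor gene (chromosome 17, 17884704 to 17885205, between genes), at 4.72 ± 0.21. Other large rises lay near the transcription factor gene Zeb2 (chromosome 2, 44956859 to 44957360, between genes) at 4.55 ± 0.24 and inside Nfkb1, which encodes an NF-kB subunit (chromosome 3, 135640212 to 135640713), at 4.26 ± 0.18. A region inside Lpp (chromosome 16, 24766325 to 24766826) rose by 4.42 ± 0.18, and 26 of the 49 regions assigned to Lpp were higher. Falls included regions inside Hsf3 (chromosome X, 96314022 to 96314523), at -2.38 ± 0.30, and near Retnla, a gene of alternatively activated macrophages (chromosome 16, 48831176 to 48831677, between genes), at -2.08 ± 0.32.

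Of the 175 regions assigned to 32 genes for inflammatory cytokines and effectors, 100 rose and 10 fell in MC (108 and 11 adjusted over the list alone). The list had a median of 0.78 and a camera adjusted p of 2.08e-16. Members included Acod1, which makes itaconate (chromosome 14, 103046654 to 103047155, within 1 kb of a gene end), at 2.78 ± 0.13. Others were Il1a (chromosome 2, 129311493 to 129311994, between genes) at 3.35 ± 0.23 and a region between genes assigned to Il12b (chromosome 11, 44389981 to 44390482) at 2.11 ± 0.12. The Il12b region within 1 kb of a gene end (chromosome 11, 44414555 to 44415056) differed by only -0.11 ± 0.16 (adjusted p = 0.675). Tnf (chromosome 17, 35201892 to 35202393, within 1 kb of a gene end) rose by 1.58 ± 0.15. In the list of NF-kB subunits and negative feedback, with 266 regions at 33 genes, 132 rose and 7 fell (138 and 7 adjusted over the list alone; camera adjusted p = 1.12e-14). The feedback genes Socs3 (chromosome 11, 117977793 to 117978294, between genes) and Irak3 (chromosome 10, 120191153 to 120191654, inside the gene) rose by 3.20 ± 0.19 and 3.85 ± 0.25. Interferon-stimulated genes, 186 regions at 47 genes, had 118 higher and 3 lower (123 and 3 adjusted over the list alone), a median of 0.69 and an adjusted p of 1.72e-19. Usp18, a negative regulator of interferon signalling (chromosome 6, 121249964 to 121250465, inside the gene), rose by 3.63 ± 0.25 and the chemokine gene Cxcl10 (chromosome 5, 92348132 to 92348633, within 1 kb of a gene end) by 2.68 ± 0.28. All 3 of these list calls held with an estimated correlation.

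Among receptors and signalling genes of the TLR and TNF pathways, 66 of 222 regions rose and 15 fell in MC (69 and 16 adjusted over the list alone; adjusted p = 0.0095). Ripk2 (chromosome 4, 16198702 to 16199203, between genes) and Nod2 (chromosome 8, 88649939 to 88650440, inside the gene), which act in sensing bacterial peptidoglycan, rose by 2.68 ± 0.19 and 2.75 ± 0.20. Of 101 regions at antigen presentation and costimulation genes, 30 rose and 4 fell (33 and 4 adjusted over the list alone; adjusted p = 0.0078), with an adjusted p = 0.461 with an estimated correlation. Cd40 (chromosome 2, 165055013 to 165055514, within 1 kb of a gene end) rose by 1.72 ± 0.16. The 20 regions of neutrophil and granulocyte genes had 7 higher and 0 lower, the same numbers adjusted over the list alone. Camp, an antimicrobial peptide gene (chromosome 9, 109849435 to 109849936, within 1 kb of a gene end), rose by 2.21 ± 0.15. That list had an adjusted p of 0.0331, an adjusted p = 0.0747 with an estimated correlation, and an adjusted p of 0.0878 without MC replicate 2. In total, limma called 14474 regions, 9510 higher and 4964 lower, of which 4628 and 766 changed at least 2-fold. With quantile normalization the split was 6711 higher and 5359 lower. Of the higher regions 8.04% lay within 1 kb of a gene end, against 22.6% of all regions.

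**Figure D1:**
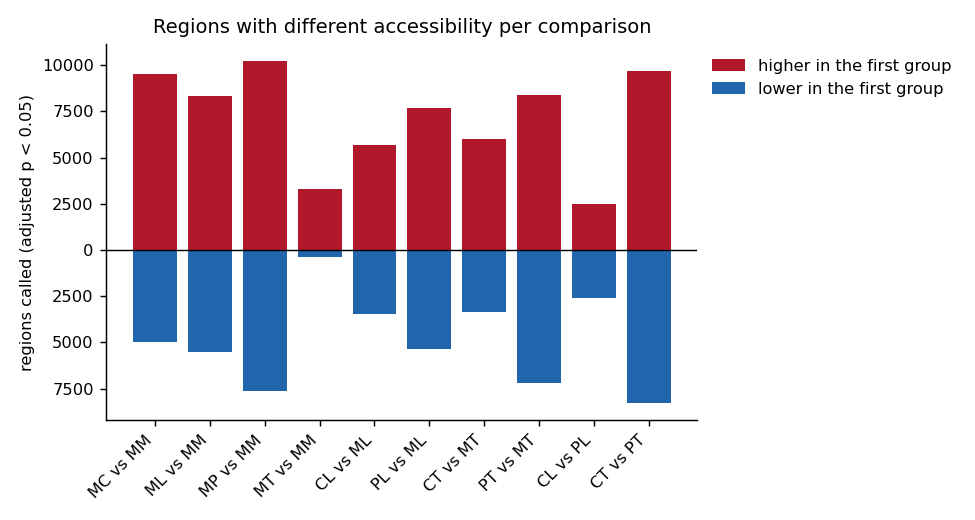
Regions called higher and lower in each comparison (horizontal axis) by limma at an adjusted p under 0.05, as numbers of regions on the vertical axis. PolyI:C alone against medium and CT against PT had the most calls, 17858 and 17962.

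LPS alone raised many of the same loci, again with Fpr1 at the top (4.02 ± 0.21) and the Nfkb1 region at 3.87 ± 0.18. Regions near Ccdc88b (chromosome 19, 6870773 to 6871274, between genes) and inside Rbbp8 (chromosome 18, 11727833 to 11728334) rose by 3.68 ± 0.21 and 3.63 ± 0.22. Hsf3 and Retnla fell, at -2.27 ± 0.30 and -2.03 ± 0.32. In the inflammatory list 91 regions rose and 5 fell (97 and 10 adjusted over the list alone; adjusted p = 2.01e-15). Acod1 rose by 2.76 ± 0.13, the neutrophil chemoattractant gene Cxcl2 (chromosome 5, 90903426 to 90903927, within 1 kb of a gene end) by 1.45 ± 0.11 and Tnf by 1.95 ± 0.15. At Il12b the distal region rose by 1.71 ± 0.12, while the one within 1 kb of a gene end fell, at -0.82 ± 0.16. NF-kB and feedback genes had 131 regions higher and 6 lower (142 and 15 adjusted over the list alone; adjusted p = 3e-17), and 33 of the 33 genes had at least 1 higher region. Tnip1, an NF-kB inhibitor gene (chromosome 11, 54953981 to 54954482, inside the gene), rose by 3.41 ± 0.22, Socs3 by 3.25 ± 0.19, and Nfkbia, the gene for another inhibitor (chromosome 12, 55492523 to 55493024, within 1 kb of a gene end), by 1.32 ± 0.13.

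Interferon-stimulated genes had 62 regions higher and 2 lower in ML (67 and 4 adjusted over the list alone; adjusted p = 1.95e-05), with an adjusted p = 0.185 with an estimated correlation. Ifit3 (chromosome 19, 34583288 to 34583789, within 1 kb of a gene end) rose by 1.35 ± 0.17. The antigen presentation list had 39 higher and 4 lower (41 and 4 adjusted over the list alone; adjusted p = 5.31e-06; adjusted p = 0.194 with an estimated correlation). Ciita, the regulator of MHC class II genes (chromosome 16, 10498057 to 10498558, inside the gene), rose by 1.89 ± 0.19. Receptor and signalling genes had 58 higher and 16 lower (63 and 17 adjusted over the list alone; adjusted p = 0.00589; adjusted p = 0.0506 with an estimated correlation). Regions of erythroid and progenitor genes went the other way, 12 lower and 3 higher of 27 (14 and 3 adjusted over the list alone; adjusted p = 0.0024; adjusted p = 0.307 with an estimated correlation). Tal1, a hematopoietic transcription factor gene (chromosome 4, 115052538 to 115053039, between genes), fell, at -0.84 ± 0.20. Limma called 13879 regions, 8355 higher and 5524 lower. Leaving out 1 library lowered the count to 7740 without ML replicate 1, 8935 without ML replicate 2 and 8046 without MM replicate 2.

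PolyI:C alone gave large rises at interferon-stimulated genes and elsewhere. Rsad2, which encodes the antiviral protein viperin (chromosome 12, 26441802 to 26442303, within 1 kb of a gene end), rose by 4.99 ± 0.29, and Ifit2, an antiviral RNA-binding protein gene (chromosome 19, 34577802 to 34578303, between genes), by 4.65 ± 0.33. A region between genes assigned to Grm5 (chromosome 7, 88166524 to 88167025) rose by 4.85 ± 0.35. The largest fall was inside Slc7a13 (chromosome 4, 19838051 to 19838552) at -3.20 ± 0.30. Others were inside Nrp1, a semaphorin co-receptor gene (chromosome 8, 128435680 to 128436181), at -2.48 ± 0.26, and Igf1, a growth factor gene (chromosome 10, 87908763 to 87909264), at -2.33 ± 0.23. Of the 186 interferon-stimulated regions 137 rose and 1 fell (144 and 3 adjusted over the list alone), with a median of 1.06 and an adjusted p of 7.75e-35. Each of the 47 genes had at least 1 higher region. Cxcl10 rose by 3.83 ± 0.28.

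Inflammatory genes had 77 regions higher and 17 lower in MP (80 and 20 adjusted over the list alone; adjusted p = 6.18e-08). Acod1 rose by 3.50 ± 0.13, the chemokine gene Ccl4 (chromosome 11, 83665699 to 83666200, between genes) by 2.32 ± 0.17, and Il6 (chromosome 5, 30012662 to 30013163, within 1 kb of a gene end) by 1.77 ± 0.15. In the NF-kB list 107 rose and 30 fell (115 and 30 adjusted over the list alone; adjusted p = 8.53e-06; adjusted p = 0.136 with an estimated correlation), with Nfkb1 at 3.79 ± 0.18. Antigen presentation genes had 49 higher and 7 lower (51 and 7 adjusted over the list alone; adjusted p = 6.18e-08; adjusted p = 0.136 with an estimated correlation). Cd40 rose by 2.17 ± 0.16 and the costimulation gene Cd86 (chromosome 16, 36598365 to 36598866, inside the gene) by 2.09 ± 0.17. Single regions fell at the scavenger receptor gene Cd36 (chromosome 5, 17835772 to 17836273, inside the gene; -2.11 ± 0.21) and the chemokine receptor gene Cx3cr1 (chromosome 9, 120037317 to 120037818, between genes; -1.55 ± 0.17), in lists that were not called. Limma called 17858 regions, 10223 higher and 7635 lower, or 7967 and 7830 with quantile normalization and 9636 and 8531 with libraries shifted to one median. The reads of the 2 MP libraries differed by no more than counting noise, with a chi-square per region of 1.003 over 53346 regions (chi-square test, p = 0.283). The pairs of the other 8 groups differed by more, from 1.07 in ML to 2.723 in PT. When the MP libraries were counted as 1 sample, 12118 regions were called, 7666 higher and 4452 lower. These 12118 were among the 17858. The values do not exclude that these are 1 library in 2 parts, so n may be 1 for MP wherever it is used, list and set tests included.

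TNF alone changed fewer regions, 3309 higher and 369 lower (limma). Tnip1 rose most, by 2.80 ± 0.22, followed by a region near Cp, the ceruloplasmin gene (chromosome 3, 19953860 to 19954361, between genes), at 2.46 ± 0.18 and the Ccdc88b region at 2.45 ± 0.21. Falls were smaller, such as Cacna1d (chromosome 14, 30250921 to 30251422, inside the gene) at -1.45 ± 0.26 and Flt1 (chromosome 5, 147574515 to 147575016, inside the gene) at -1.40 ± 0.27. NF-kB and feedback genes had 65 regions higher and 4 lower (72 and 8 adjusted over the list alone; adjusted p = 3.02e-10; adjusted p = 0.0624 with an estimated correlation), with Nfkb1 at 2.06 ± 0.18. In the inflammatory list 39 rose and 0 fell of 175 (49 and 4 adjusted over the list alone; adjusted p = 9.15e-07), with Acod1 at 2.14 ± 0.13 and Tnf at 1.06 ± 0.15. Interferon-stimulated genes were not called as a list, with 11 of 186 regions higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.978). Antigen presentation genes had 12 higher and 2 lower (14 and 3 adjusted over the list alone; adjusted p = 0.0258; adjusted p = 0.622 with an estimated correlation), a call lost without MM replicate 1 (adjusted p of 0.165) or MT replicate 1 (0.0821). The total of 3678 fell to 1983 with quantile normalization, 2210 without MM replicate 2, 2294 without MT replicate 1 and 2250 without MT replicate 2.

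**Figure D2:**
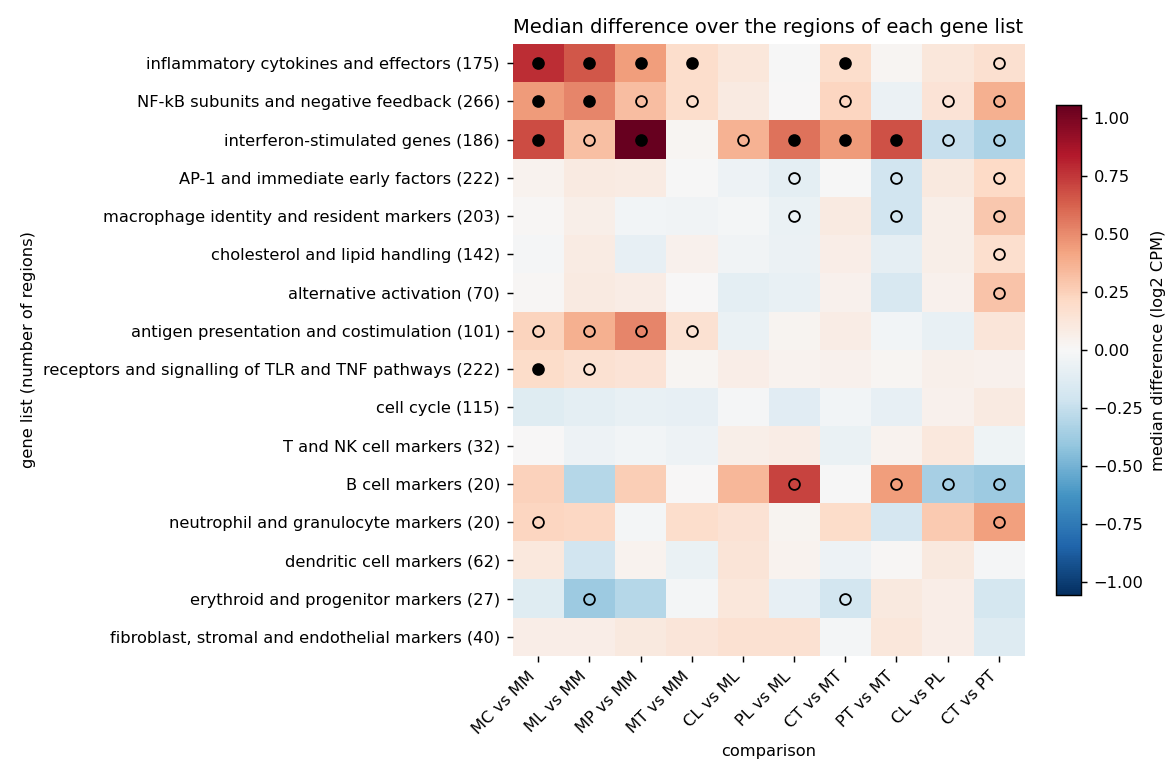
Median log2 CPM difference of the regions of each fixed gene list (vertical axis) in each comparison (horizontal axis), as color, with circles where the camera adjusted p was under 0.05 and filled circles where it also was with an estimated correlation. The median of the interferon-stimulated genes was 1.06 in MP and 0.02 in MT against medium, and -0.32 in CT against PT.

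The responses to the 4 single stimuli were compared with each other over all regions. Of the 3309 regions higher with TNF, 3076 (93%) were also higher with LPS, against 514 for independent lists. The log2 differences correlated across regions at 0.782, against 0.5 for simulated unchanged groups that share the MM libraries. CpG and LPS shared 6158 higher regions, against 1477 for independent lists, at a correlation of 0.822 (0.499 simulated) and a covariance of 0.2975 (0.0227 simulated). CpG and polyI:C shared 5841 (1807 independent), at a correlation of 0.667 (0.499 simulated) and a covariance of 0.3002 (0.0226 simulated). Each comparison uses the 2 MM libraries, so part of the excess over independent lists may come from them, and the controls were too few to split. With quantile normalization TNF and LPS shared 1731 higher regions, CpG and LPS 4017, and CpG and polyI:C 3694.

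**Figure D3:**
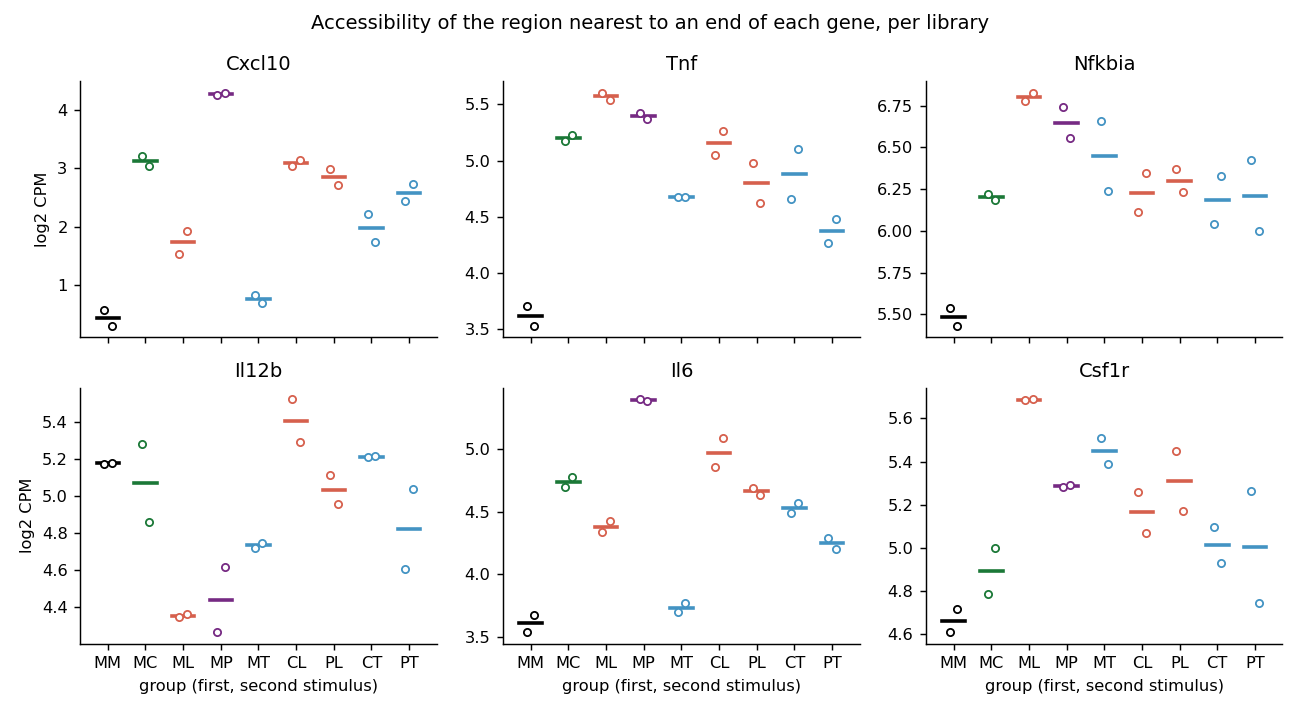
Log2 CPM of 1 region near each of the named genes in the 9 groups, with the 2 libraries as points and the group mean as a bar. Cxcl10 is highest with polyI:C alone, where it was 3.83 above medium.

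Prior CpG was tested against prior medium under the same second stimulus, LPS. The largest rise in CL over ML lay inside Svil, which encodes an actin-binding protein (chromosome 18, 5085333 to 5085834), at 3.44 ± 0.42. Rises followed at the acute phase gene Saa3 (chromosome 7, 46711410 to 46711911, within 1 kb of a gene end), at 3.36 ± 0.37 and inside Usp25, a deubiquitinase gene (chromosome 16, 77068329 to 77068830), at 3.26 ± 0.29. Falls were seen near Frmd8 (chromosome 19, 5812015 to 5812516, between genes; -1.69 ± 0.22) and inside Cyth1 (chromosome 11, 118212572 to 118213073; -1.46 ± 0.19). Interferon-stimulated genes were the only list called over all assigned regions, with 64 of 186 regions higher and 4 lower (74 and 4 adjusted over the list alone). Its median was 0.37, with an adjusted p of 9.71e-11 and an adjusted p = 0.112 with an estimated correlation. The chemokine gene Ccl5 (chromosome 11, 83524538 to 83525039, within 1 kb of a gene end) rose by 2.73 ± 0.33, Usp18 by 1.88 ± 0.25 and Cxcl10 by 1.36 ± 0.28.

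Inflammatory genes were split in CL against ML, with 35 regions higher, 16 lower and 124 not called (42 higher and 22 lower adjusted over the list alone; adjusted p = 0.352). Il12b within 1 kb of a gene end rose by 1.05 ± 0.16 and a distal Il6 region (chromosome 5, 29972732 to 29973233, between genes) by 1.71 ± 0.26, while an Acod1 region (chromosome 14, 103058961 to 103059462, between genes) fell, at -0.77 ± 0.10. In the NF-kB list 55 rose and 19 fell (60 and 21 adjusted over the list alone; adjusted p = 0.352). A region of the anti-inflammatory cytokine gene Il10 (chromosome 1, 130997469 to 130997970, between genes) rose by 1.84 ± 0.24. In the AP-1 list Batf (chromosome 12, 85700737 to 85701238, inside the gene) rose by 2.71 ± 0.32 and Fos (chromosome 12, 85472014 to 85472515, between genes) fell, at -0.96 ± 0.18. The list had 18 regions higher and 24 lower of 222 (the same numbers adjusted over the list alone; adjusted p = 0.337). Limma called 9127 regions, 5671 higher and 3456 lower. With libraries shifted to one median the split was 4231 higher and 5804 lower and with quantile normalization 4464 and 4156, so the balance of rises and falls was not fixed by these data. Without CL replicate 1, CL replicate 2, ML replicate 1 or ML replicate 2 the count was 3883, 5597, 3851 or 4744, and 5827 (2881 higher and 2946 lower) with only regions of higher mean level.

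Prior polyI:C before LPS gave rises near Bace2, a protease gene (chromosome 16, 97445282 to 97445783, between genes), of 3.63 ± 0.24, near Ifit2 of 3.34 ± 0.33 and inside Cog4 (chromosome 8, 110863938 to 110864439) of 3.32 ± 0.26 over ML. A region inside Tex14 (chromosome 11, 87462379 to 87462880) fell, at -2.25 ± 0.15, as did one inside Pacsin2 (chromosome 15, 83417423 to 83417924), at -2.20 ± 0.23. Interferon-stimulated genes had 101 regions higher and 3 lower (110 and 3 adjusted over the list alone), a median of 0.58 and an adjusted p of 1.83e-20, and the call held with an estimated correlation. Rsad2 rose by 2.88 ± 0.29, the nuclease gene Isg20 (chromosome 7, 78913588 to 78914089, within 1 kb of a gene end) by 1.65 ± 0.13 and Ccl5 by 3.30 ± 0.33.

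Tnf fell in PL against ML, at -0.77 ± 0.15, and so did Cxcl2, at -0.61 ± 0.11, while Il12b within 1 kb of a gene end rose by 0.68 ± 0.16 and a second Acod1 region (chromosome 14, 103057817 to 103058318, between genes) by 2.08 ± 0.23. The inflammatory list had 35 higher and 32 lower (38 and 34 adjusted over the list alone; adjusted p = 0.783). Falls outnumbered rises in the macrophage identity list, 46 to 20 of 203 regions (50 to 23 adjusted over the list alone; adjusted p = 0.0216; adjusted p = 0.649 with an estimated correlation). Cebpa, a myeloid transcription factor gene (chromosome 7, 35118923 to 35119424, within 1 kb of a gene end), was at -1.02 ± 0.13 and the lipid receptor gene Trem2 (chromosome 17, 48346163 to 48346664, within 1 kb of a gene end) at -0.89 ± 0.16. The AP-1 list likewise had 45 lower and 18 higher (46 and 20 adjusted over the list alone; adjusted p = 0.00952; adjusted p = 0.649 with an estimated correlation), with Bach1 (chromosome 16, 87689223 to 87689724, between genes) at -1.04 ± 0.13. Both calls were lost without PL replicate 2 (adjusted p of 0.0746 for each) and the macrophage identity call also without ML replicate 1 (0.0659). Limma called 13038 regions, 7668 higher and 5370 lower, and 6378 higher and 6919 lower with libraries shifted to one median. With only regions of higher mean level the split was 4204 higher and 4647 lower. The count was 6762 without ML replicate 1, 7827 without ML replicate 2, 8190 without PL replicate 1 and 7226 without PL replicate 2.

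With TNF as the second stimulus, prior CpG raised a region inside Fggy, a carbohydrate kinase gene (chromosome 4, 95736571 to 95737072), by 4.31 ± 0.26, the Cacna1d region by 4.21 ± 0.26 and a region near Uaca (chromosome 9, 60899704 to 60900205, between genes) by 3.96 ± 0.26. Falls included Medag (chromosome 5, 149374039 to 149374540, inside the gene) at -1.76 ± 0.21 and Shank2 (chromosome 7, 144417508 to 144418009, inside the gene) at -1.70 ± 0.23. Interferon-stimulated genes had 73 regions higher and 3 lower in CT against MT (89 and 6 adjusted over the list alone), with a median of 0.45 and an adjusted p of 5.62e-13. Oasl1, a gene of the oligoadenylate synthetase family (chromosome 5, 114922986 to 114923487, within 1 kb of a gene end), rose by 2.28 ± 0.19 and Usp18 by 2.77 ± 0.25. Inflammatory genes had 48 higher and 16 lower (53 and 18 adjusted over the list alone; adjusted p = 0.00109). Among them were Lcn2, a siderophore-binding protein gene (chromosome 2, 32387750 to 32388251, within 1 kb of a gene end), at 2.73 ± 0.34 and Il6 at 0.80 ± 0.15. The Tnf region differed by 0.21 ± 0.15 (adjusted p = 0.4). Both calls held with an estimated correlation.

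NF-kB and feedback genes had 88 regions higher and 7 lower in CT against MT (97 and 10 adjusted over the list alone; adjusted p = 1.03e-06; adjusted p = 0.135 with an estimated correlation). Members were a distal Nfkbia region (chromosome 12, 55467527 to 55468028, between genes) at 3.57 ± 0.27 and Tnip1 (chromosome 11, 54936013 to 54936514, inside the gene) at 1.55 ± 0.16. In the AP-1 list, not called as a whole (adjusted p = 0.824), 28 rose and 13 fell (the same numbers adjusted over the list alone). Higher members were Klf6 (chromosome 13, 5828588 to 5829089, between genes) at 2.77 ± 0.17 and Batf (chromosome 12, 85703383 to 85703884, inside the gene) at 3.58 ± 0.31. Erythroid and progenitor genes had 3 lower and 2 higher regions of 27 (6 and 2 adjusted over the list alone; adjusted p = 0.0355; adjusted p = 0.729 with an estimated correlation), a call lost without CT replicate 2 (0.321) or MT replicate 2 (0.322). Limma called 9355 regions, 6029 higher and 3326 lower, against 5199 and 4501 with libraries shifted to one median and 4598 and 3814 with quantile normalization. Leaving out CT replicate 2 gave 5169, MT replicate 1 gave 6181 and MT replicate 2 gave 5285, and regions of higher mean level alone gave 6062.

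Prior polyI:C before TNF raised Rsad2 by 3.83 ± 0.29, the second Acod1 region by 3.75 ± 0.23, Ifit2 by 3.72 ± 0.33 and Bace2 by 3.56 ± 0.24 over MT. Falls included regions inside Lhx1 (chromosome 11, 84522507 to 84523008) at -2.55 ± 0.23, and inside Ap1b1 (chromosome 11, 5012302 to 5012803) at -2.18 ± 0.23. Of the interferon-stimulated regions 112 rose and 1 fell (119 and 2 adjusted over the list alone), with a median of 0.67 and an adjusted p of 6.92e-26, and the call held with an estimated correlation. Oasl1 rose by 2.77 ± 0.19 and Cxcl10 by 1.82 ± 0.28.

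Regions of macrophage identity genes fell more often than they rose in PT against MT, 58 to 17 (59 to 17 adjusted over the list alone; adjusted p = 0.00182; adjusted p = 0.492 with an estimated correlation). Cebpa was at -1.12 ± 0.13, the scavenger receptor gene Cd163 (chromosome 6, 124273199 to 124273700, between genes) at -0.94 ± 0.12 and Cx3cr1 at -1.24 ± 0.17. The AP-1 list had 50 lower and 16 higher, unchanged in number adjusted over the list alone (adjusted p = 0.0119; adjusted p = 0.706 with an estimated correlation), with Myc (chromosome 15, 61985243 to 61985744, within 1 kb of a gene end) at -1.04 ± 0.16. Inflammatory and NF-kB lists were divided, at 33 higher and 30 lower (34 and 30 adjusted over the list alone; adjusted p = 0.81) and 39 higher and 50 lower (41 and 50 adjusted over the list alone; adjusted p = 0.473). A distal Il1b region (chromosome 2, 129360143 to 129360644, between genes) fell, at -1.34 ± 0.20, as did a distal Socs3 region (chromosome 11, 117946419 to 117946920, between genes), at -1.17 ± 0.15, while Nfkb1 rose by 1.64 ± 0.18. PT replicate 2 stood apart from PT replicate 1, and without it the macrophage identity list had an adjusted p of 0.0749 and the AP-1 list 0.285 (0.0966 without MT replicate 1). Without PT replicate 1 the NF-kB list passed, with an adjusted p of 0.0403 and a median of -0.17, as did the cholesterol list (0.0354) and the alternative activation list (0.026), both downward. Limma called 15618 regions, 8403 higher and 7215 lower. The balance turned to 7488 higher and 8499 lower with libraries shifted to one median, 6859 and 7375 with quantile normalization, 4903 and 6125 with only regions of higher mean level, and 9796 and 9910 without PT replicate 1. The count was 9660 without PT replicate 2, 8559 without MT replicate 1, 19706 without PT replicate 1 and 7560 with only these 4 libraries in the fit.

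Regions opened by a single stimulus were then followed in the libraries with 2 stimuli, using sets defined in libraries outside each comparison. The 9510 regions that CpG alone opened were shifted upward in CL against ML, with a median of 0.40, 3317 higher and 218 lower (camera adjusted p = 6.41e-23). The same set was shifted upward in CT against MT, with a median of 0.50, 4132 higher and 79 lower (adjusted p = 6.19e-46). The 10223 regions that polyI:C alone opened had medians of 0.42 in PL against ML, with 4144 higher and 384 lower (camera adjusted p = 6.01e-22), and 0.48 in PT against MT, with 4691 higher and 374 lower (adjusted p = 8.82e-29). Regions closed by the same stimulus alone were shifted downward, with medians of -0.23 and -0.33 for the 4964 regions of CpG in CL against ML and CT against MT, and -0.22 and -0.28 for the 7635 regions of polyI:C in PL against ML and PT against MT. The regions of the stimulus not received moved up as well, the polyI:C set by a median of 0.21 in CL against ML and 0.28 in CT against MT, and the CpG set by 0.32 in PL against ML and 0.37 in PT against MT. These sets overlap, with 5841 regions in both, so their rises are not separate results. The calls in this paragraph held with an estimated correlation. No group received a first stimulus followed by medium, so accessibility left from the first stimulus and a changed response to the second cannot be separated here.

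**Figure D4:**
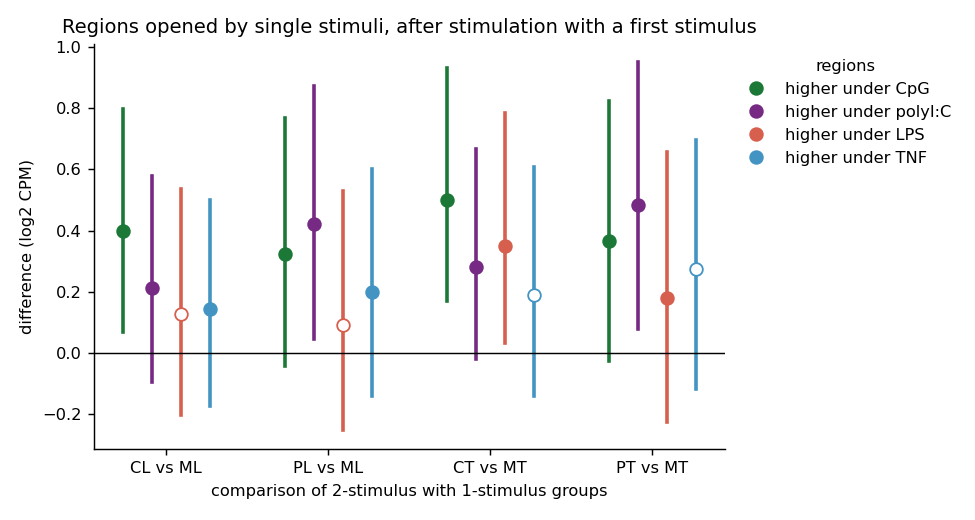
Log2 CPM difference (vertical axis) of sets of regions opened by a single stimulus, in the 4 comparisons of a first stimulus with medium under the same second stimulus (horizontal axis). Dots are medians, lines run from the lower to the upper quartile, and open dots are sets that share libraries with the comparison, such as the LPS-opened set in CL against ML, with a median of 0.13 against -0.04 in simulated unchanged groups.

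The effects of a first stimulus under LPS and under TNF were also compared. For CpG, 3137 regions were higher in both CL against ML and CT against MT, against 636 for independent lists, and the log2 differences, which share no library, correlated across regions at 0.659. For polyI:C, 5321 were higher in both PL against ML and PT against MT (1198 independent), at a correlation of 0.829. Under LPS, 3203 regions were higher after both CpG and polyI:C (808 independent; correlation 0.676, 0.5 simulated; covariance 0.1607, 0.0227 simulated). Under TNF the number was 2683 (942 independent; correlation 0.433, 0.499 simulated; covariance 0.1213, 0.0227 simulated), or 1622 with quantile normalization.

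The difference of the CpG effect between LPS and TNF was tested as an interaction. It was called at 171 regions, 160 with a lower CpG effect under LPS and 11 with a higher one. At Uaca the difference was -3.26 ± 0.36 and at Pdss1, a coenzyme Q synthesis gene (chromosome 2, 22933555 to 22934056, inside the gene), -2.75 ± 0.20. It was, at Foxp1 (chromosome 6, 99050455 to 99050956, inside the gene), -2.35 ± 0.33 and, at the distal Nfkbia region, -2.15 ± 0.38. Members of the fixed lists among the 171 included Lcn2 (-2.12 ± 0.48), Klf6 (-1.44 ± 0.24), the distal Il12b region (-1.13 ± 0.17) and Otulin, a deubiquitinase gene (chromosome 15, 27625296 to 27625797, inside the gene; -1.03 ± 0.15). The NF-kB list was shifted downward in the interaction, with 6 regions lower and 0 higher (13 and 0 adjusted over the list alone; adjusted p = 0.000182; adjusted p = 0.401 with an estimated correlation). The inflammatory list had 4 lower and 0 higher (10 and 1 adjusted over the list alone; adjusted p = 0.0422) and the AP-1 list 2 lower and 0 higher (the same adjusted over the list alone; adjusted p = 0.0157), with adjusted p = 0.401 and adjusted p = 0.415 with an estimated correlation. The macrophage identity list (1 lower and 0 higher, the same adjusted over the list alone; adjusted p = 0.0157; adjusted p = 0.401 with an estimated correlation) was also shifted downward. So was the alternative activation list (0 called, 0 adjusted over the list alone; adjusted p = 0.0157; adjusted p = 0.415 with an estimated correlation). The erythroid list was shifted upward (0 called, 1 higher adjusted over the list alone; adjusted p = 0.00164; adjusted p = 0.401 with an estimated correlation). Voom on recovered reads called 400 regions (44 higher and 356 lower) and the fit of these 8 libraries alone 928 (203 higher and 725 lower). Quantile normalization gave 101 (8 higher and 93 lower) and limma without the variance trend 65 (5 higher and 60 lower). The share of higher regions thus depended on the fit. Leaving out 1 library gave 62 (CL replicate 1), 75 (CL replicate 2), 52 (CT replicate 2), 58 (ML replicate 1), 92 (ML replicate 2), 279 (MT replicate 1) and 77 (MT replicate 2).

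For polyI:C the same interaction was called at 0 regions by limma and at 0 by voom on recovered reads. Of the 53796 regions, 2819 had an unadjusted limma p under 0.05, near the number that this threshold passes when nothing differs. The interferon-stimulated list was shifted downward by a median of -0.11, with 0 regions called (0 higher and 6 lower adjusted over the list alone; adjusted p = 0.000302; adjusted p = 0.734 with an estimated correlation). Without PT replicate 1 the count was 371, without PT replicate 2 it was 6 and without MT replicate 1 it was 2. In simulated data 30% of planted log2 changes of 1 and 86% of changes of 2 were recovered in this interaction. That simulation gave all libraries the same dispersion, while the PT replicates differed more than those of other groups. Recovery in the data may therefore be lower.

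CpG and polyI:C as first stimuli were compared with each other under LPS. CL was above PL near Rnf24 (chromosome 2, 131364575 to 131365076, between genes), at 2.55 ± 0.29, at Svil, at 2.89 ± 0.42, and at Saa3 (chromosome 7, 46712169 to 46712670, within 1 kb of a gene end), at 2.03 ± 0.27. It was below PL at Grm5, at -2.55 ± 0.35, and at the acetyltransferase gene Nat10 (chromosome 2, 103721749 to 103722250, within 1 kb of a gene end), at -2.55 ± 0.37. Interferon-stimulated genes were lower in CL, with 24 regions lower and 3 higher (31 and 3 adjusted over the list alone; adjusted p = 2.07e-06; adjusted p = 0.192 with an estimated correlation). Isg20 was among them, at -0.74 ± 0.13. NF-kB and feedback genes were higher, with 31 regions higher and 6 lower (35 and 7 adjusted over the list alone; adjusted p = 0.00702; adjusted p = 0.441 with an estimated correlation). Nfkbiz, an NF-kB regulator gene (chromosome 16, 55795584 to 55796085, between genes), was at 1.04 ± 0.22. Tlr9, the gene of the CpG receptor (chromosome 9, 106222318 to 106222819, within 1 kb of a gene end), was lower, at -1.06 ± 0.16. Limma called 5075 regions, 2489 higher and 2586 lower, or 2099 and 3070 with libraries shifted to one median. It called 1911, 2084, 2241 or 1784 without CL replicate 1, CL replicate 2, PL replicate 1 or PL replicate 2. The count was 7671 with quantile normalization, 8159 with only these 4 libraries in the fit and 3098 with only regions of higher mean level.

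Under TNF the same comparison gave differences at Fggy, with CT above PT by 4.70 ± 0.26, and at Ikzf1, a hematopoietic transcription factor gene (chromosome 11, 11744253 to 11744754, inside the gene), by 3.58 ± 0.24. CT was below PT at Grm5, at -3.11 ± 0.35, and at the guanylate-binding protein gene Gbp4 (chromosome 5, 105141379 to 105141880, between genes), at -2.72 ± 0.32. Of the NF-kB regions 103 were higher and 12 lower (108 and 12 adjusted over the list alone; adjusted p = 1.82e-07; adjusted p = 0.142 with an estimated correlation), with the distal Nfkbia region at 2.78 ± 0.27. Macrophage identity genes had 67 higher and 7 lower (68 and 7 adjusted over the list alone; adjusted p = 2.85e-05; adjusted p = 0.144 with an estimated correlation). Cx3cr1 was at 1.21 ± 0.17 and the integrin gene Itgam (chromosome 7, 128048663 to 128049164, between genes) at 1.42 ± 0.18. Interferon-stimulated genes were lower in CT at 63 regions and higher at 11 (63 and 12 adjusted over the list alone; adjusted p = 4.48e-06; adjusted p = 0.144 with an estimated correlation). Rsad2 was at -2.25 ± 0.29 but Usp18 at 2.10 ± 0.25.

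AP-1 and immediate early genes had 64 regions higher and 19 lower in CT against PT (66 and 21 adjusted over the list alone; adjusted p = 0.00295; adjusted p = 0.348 with an estimated correlation). Batf was at 3.39 ± 0.31, Klf6 at 2.43 ± 0.17 and Nr4a1 (chromosome 15, 101262482 to 101262983, inside the gene) at 1.30 ± 0.15. The inflammatory list had 57 higher and 29 lower (61 and 31 adjusted over the list alone; adjusted p = 0.0423; adjusted p = 0.149 with an estimated correlation). Csf2 (chromosome 11, 54201207 to 54201708, between genes), the gene of the growth factor GM-CSF, was at 2.18 ± 0.24. Alternative activation genes had 28 higher and 8 lower of 70 (29 and 8 adjusted over the list alone; adjusted p = 0.0044; adjusted p = 0.348 with an estimated correlation), with Pdcd1lg2 (chromosome 19, 29485300 to 29485801, between genes) at 1.68 ± 0.18. Cholesterol and lipid genes had 37 higher and 11 lower of 142, the same numbers adjusted over the list alone (adjusted p = 0.0363; adjusted p = 0.413 with an estimated correlation), with the lipid exporter gene Abca1 (chromosome 4, 53126784 to 53127285, inside the gene) at 2.16 ± 0.26. Without PT replicate 2 the adjusted p was 0.0657 for AP-1, 0.0705 for inflammatory, 0.0742 for alternative activation and 0.332 for cholesterol genes. Without CT replicate 2 it was 0.0789 for inflammatory and 0.0768 for cholesterol genes, and with quantile normalization 0.0559 for inflammatory genes. Limma called 17962 regions, 9691 higher and 8271 lower. The count was 7891 without CT replicate 2, 8778 without PT replicate 2 and 8063 with only these 4 libraries in the fit.

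**Figure D5:**
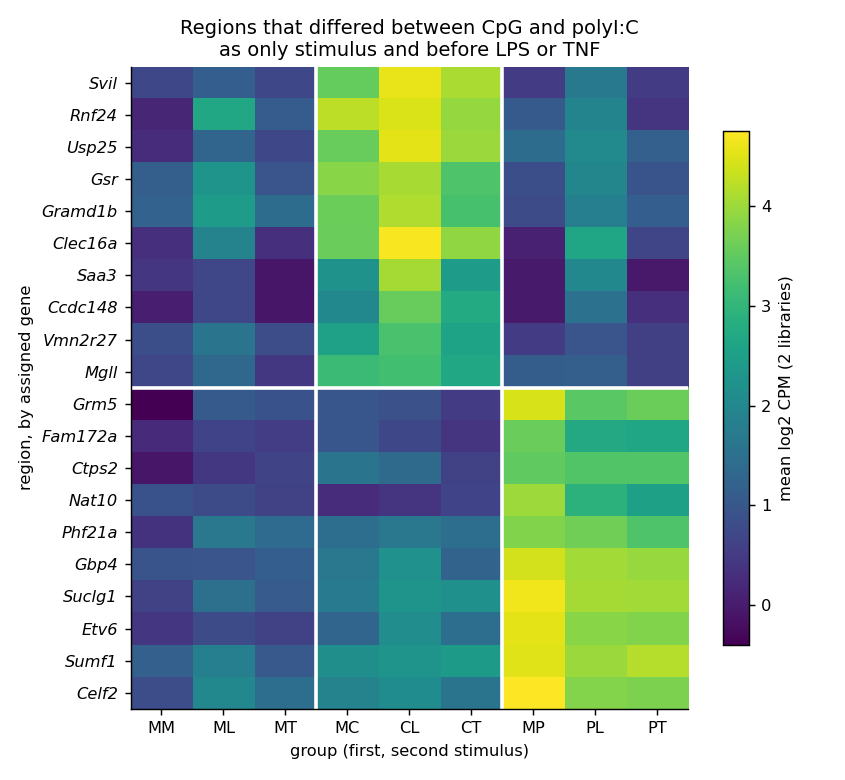
Log2 CPM in the 9 groups of regions that differed between CpG and polyI:C as stimuli, with the group means of 2 libraries. Svil lies at 3.55 in MC, 4.58 in CL and 4.10 in CT, and at 0.49 in MP, 1.69 in PL and 0.49 in PT.

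Marker lists of other cell types were tested in all 10 comparisons between groups. B cell genes, with 20 regions at 4 genes, were not called in MP against MM, with 7 higher and 3 lower (the same adjusted over the list alone; adjusted p = 0.252). With polyI:C as first stimulus they had 10 higher and 1 lower in PL against ML (12 and 1 adjusted over the list alone; adjusted p = 0.00413; adjusted p = 0.3 with an estimated correlation) and 8 higher and 1 lower in PT against MT (9 and 2 adjusted over the list alone; adjusted p = 0.0126; adjusted p = 0.492 with an estimated correlation; 0.0965 without PT replicate 2; 0.136 with regions assigned by the nearest gene end). They were lower in CL against PL, with 4 lower and 0 higher (the same adjusted over the list alone; adjusted p = 0.00108; adjusted p = 0.192 with an estimated correlation), and in CT against PT, with 7 lower and 0 higher (8 and 0 adjusted over the list alone; adjusted p = 0.00295; adjusted p = 0.144 with an estimated correlation). With only regions within 1 kb of a gene end, the B cell median turned to -0.547 in PL against ML, -0.37 in PT against MT and 0.24 in CL against PL, without a call. A region inside Bank1, a B cell scaffold gene (chromosome 3, 136146012 to 136146513), was at 2.54 ± 0.29 in MP against MM, 2.39 ± 0.29 in PL against ML and 2.91 ± 0.29 in PT against MT. Neutrophil genes were higher in CT against PT, with 5 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.0129; adjusted p = 0.142 with an estimated correlation), with the granulocyte receptor gene Csf3r (chromosome 4, 126003936 to 126004437, between genes) at 1.62 ± 0.16. The lists of T and NK cell, dendritic cell, fibroblast and cell cycle genes were called in none of the 10 comparisons by camera over all assigned regions. With regions assigned by the nearest gene end, however, the fibroblast list was called in MT against MM (median 0.16; camera adjusted p = 0.0337). With only regions within 1 kb of a gene end, camera called the cell cycle list lower in MC, ML and MP against MM (adjusted p of 0.0099, 0.00836 and 0.0251). In MC against medium, for example, T and NK cell genes had 7 regions higher and 2 lower of 32 (7 and 3 adjusted over the list alone), dendritic cell genes 17 and 8 of 62 (20 and 9 adjusted over the list alone), fibroblast, stromal and endothelial genes 11 and 1 of 40 (12 and 1 adjusted over the list alone) and cell cycle genes 14 and 9 of 115 (the same adjusted over the list alone).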

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

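The tests of depth, of mixed libraries, of single libraries and of prior opening were written after the patterns were seen and before their results, and the shared axis test was written after its result. The CpG effect differed between LPS and TNF as second stimuli at 171 regions, a difference between groups found by an interaction test, with 6922 regions at an unadjusted p under 0.05. The difference between CpG and polyI:C as first stimuli also differed between the second stimuli, at 462 regions (85 with a higher and 377 with a lower CpG minus polyI:C value under LPS), in a contrast added after seeing the data, with 9243 at an unadjusted p under 0.05. Its named members include Fggy (-3.32 ± 0.37), Batf (-3.03 ± 0.43) and Pdss1 (-2.52 ± 0.20). Leaving out 1 library gave 59 (CL replicate 1), 139 (CL replicate 2), 58 (CT replicate 2), 82 (PL replicate 1), 122 (PL replicate 2), 150 (PT replicate 2) and 8887 (PT replicate 1), so this count depends on single libraries, with 638 without CT replicate 1.

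The 160 regions with a lower CpG effect under LPS were weighed against 2 explanations. Whether 1 library decided them cannot be told: 100% stayed below 0 whichever of the 8 libraries was left out, but these libraries chose the regions, which nearly fixes that outcome, and the count of called regions fell to 52 without CT replicate 2. CpG alone, in libraries outside the interaction, opened 90% of them (144 regions; median 2.12), and the median was 1.66 for LPS alone and 0.24 for TNF alone. CL and CT lay level (median -0.05), so these regions, Uaca and the distal Nfkbia region among them, may be open after CpG under either second stimulus, with LPS alone already opening them in part. The median of CL against ML was still 0.456 at these regions, with 71 called higher and 20 lower. ML lay above MT at 100% of the regions. The choice of regions by the CL, ML, CT and MT libraries partly forces this share and the medians that use these libraries, those of LPS alone and TNF alone included.

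PT replicate 2 lay apart from PT replicate 1, with an SD of the replicate difference of 0.438 at equal depth against at most 0.35 in the other groups, so its lower depth does not account for the gap. A swap for another group would place it closest to that group, but it correlated at 0.919 with PT replicate 1 and at most at 0.873 with another group's library. It correlated less well than PT replicate 1 with 16 of 16 libraries of other groups. Its larger spread would lower each of these correlations, so they cannot exclude a partial mix. The replicate difference in PT correlated at -0.358 with that in CT, -0.26 with that in MC and 0.242 with that in MT, which could come from a preparation difference shared by PT with other groups. No biological explanation was tested, as the labels give none.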

How the results depend on the processing

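Voom, the nearest gene end, the MP libraries as 1 sample and the list tests with libraries left out were chosen after seeing the data. Counts of called regions stayed within 1.5 times under log2(CPM + 1), robust variances, libraries shifted to one median and the replicate block, and the cause was not tested for any move named here unless fewer regions or libraries were used. Quantile normalization gave 1983 regions in MT against MM, 7671 in CL against PL, 101 in the CpG interaction and 1 in the polyI:C interaction. It gave 4017 regions higher in both MC and ML, 3694 in MC and MP, 1504 in MC and MT, 3530 in ML and MP, 1731 in ML and MT, 1559 in MP and MT, and 1622 in both CT and PT against MT. Keeping only regions of higher mean level, with 40347 left to test, gave 5827 in CL against ML, 6062 in CT against MT and 3098 in CL against PL. With only the compared groups in the fit, 7560 regions were called in PT against MT, 8159 in CL against PL, 8063 in CT against PT and 928 in the CpG interaction, which had 65 without the variance trend and 400 with voom.

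Leaving out 1 library, with the lone sample of a group assumed to vary like the others, gave 10025 to 10858 regions in MC, 7740 to 9719 in ML, 12816 to 13577 in MP and 2210 to 2773 in MT against MM. It gave 3851 to 5597 in CL and 6762 to 8190 in PL against ML, and 5169 to 6455 in CT and 8559 to 19706 in PT against MT. The range was 1784 to 2241 in CL against PL, 7891 to 22708 in CT against PT, 52 to 279 in the CpG interaction and 0 to 371 in the polyI:C interaction. The highest values in PT against MT and CT against PT came without PT replicate 1, and counts fall in part because fewer libraries are fitted.

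Of the 160 list tests in the comparisons between groups 44 were called, 37 to 48 with 1 library left out, and 13 with an estimated correlation, where the lists of interferon-stimulated and inflammatory genes kept most of their calls. The lists called in the interactions lost their calls with an estimated correlation and were not tried under other alternatives. With only regions within 1 kb of a gene end, 129 list results were the same, 16 gained and 12 lost a call, and 3 turned around. The 3 were B cell genes, with 2 such regions, at -0.547 in PL against ML, -0.37 in PT against MT and 0.24 in CL against PL. Near gene ends the inflammatory list was higher in CL against ML (adjusted p = 0.00482), macrophage identity genes were lower there (0.00634), and cell cycle genes were lower in MC (0.0099), ML (0.00836) and MP (0.0251). Inflammatory (0.000369), AP-1 (0.000264) and erythroid genes (0.00437) were higher in CL against PL and receptors in MP (0.0081). Erythroid genes were lower in MC (0.0131), MP (0.00691) and PL against ML (0.0261), and cholesterol and alternative activation genes in PL against ML (0.0119, 0.0156) and PT against MT (0.0304, 0.0308). Calls lost near gene ends were antigen presentation (0.0505), receptors (0.0538) and neutrophil genes (0.0554) in MC, receptors in ML (0.199), inflammatory genes in MT (0.237), NF-kB (0.117) and erythroid genes (0.106) in CT against MT, and NF-kB in CL against PL (0.0798). In CT against PT the lists lost were cholesterol (0.23), alternative activation (0.371), B cell (0.908) and neutrophil genes (0.125). Quantile normalization ended the inflammatory call in CT against PT (0.0559) and added AP-1 (0.0254) and B cell genes (0.0441) in ML and receptors in MT (0.0269). The nearest gene end ended the B cell call in PT against MT (0.136) and added receptors (0.044) and fibroblast genes (0.0337) in MT. Of the set tests 25 of 32 were called, 24 with quantile normalization and 30 with sets of at least 2-fold, where the 52 regions lower with TNF turned to a median of 0.263 in PL against ML. Of 802 named results, each a region in a comparison between groups, 24 lost their call with quantile normalization, 21 without the variance trend, 10 with only the compared groups and 5 with voom. Leaving out each library in turn ended the call in 244 cases, started one in 8 and left 2956 the same.

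No pairing of the libraries by replicate number was established: over 36 pairs of groups the replicate differences correlated at -0.358 to 0.242, with 5 over 0.1. This does not exclude a pairing. The replicates of MP, ML and MM differed by little more than counting noise (chi-square per region 1.003, 1.07 and 1.081). A shared origin could therefore leave no correlation there. The replicate block gave 14346 regions in MC, 13697 in ML, 17733 in MP and 3603 in MT against MM, 8943 in CL and 12822 in PL against ML, 9168 in CT and 15447 in PT against MT, 4921 in CL against PL, 17758 in CT against PT, 157 in the CpG interaction and 0 in the polyI:C interaction. In the comparisons between groups it changed no call of a named region, list or set. Of the 157 regions it called in the CpG interaction 6 were higher, and 155 were among the 171. The motif alternatives were not run, since the motif tests were not. With 2 libraries per group and 200 of 53796 regions changed, 4% of simulated log2 changes of 0.5 were recovered in MC against MM. That simulation called 140 regions, against 14474 in the data. Adjustment over all regions is stricter when fewer regions change, so the 4% does not give the recovery in the data. The part of depth in it was not tested.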

Other observations

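The contrasts used here were added after seeing the data, and the tests of the explanations were written before their results. CpG alone and polyI:C alone differed at 11898 regions, 6524 higher with CpG and 5374 higher with polyI:C (limma). The count was 7388 without MC replicate 1, 7413 without MP replicate 1, 7449 without MP replicate 2 and 8018 without MC replicate 2. Regions higher with CpG included Clec16a, a regulator of mitophagy (chromosome 16, 10584806 to 10585307, inside the gene), by 3.50 ± 0.32, and Gsr, the glutathione reductase gene (chromosome 8, 33655196 to 33655697, inside the gene), by 3.02 ± 0.33. Regions higher with polyI:C included Grm5, at -3.47 ± 0.35 for CpG minus polyI:C, and the transcription factor gene Etv6 (chromosome 6, 134225401 to 134225902, inside the gene), at -3.28 ± 0.31. LPS and TNF alone differed at 2777 regions, 1934 of them higher with LPS, and CL and CT differed at 186, of which 132 were higher in CL. At an unadjusted limma p under 0.05 there were 11596 and 6090 regions. These 2 counts do not test the change between the comparisons, which is the CpG interaction, called at 171 regions. Neither count was tried with a library left out.

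The regions that differ between 4 h of CpG and 4 h of polyI:C alone were looked up in other cells, which received CpG or polyI:C first and then LPS or TNF, in libraries not used to find the regions. If a difference of that kind were present after the second stimulus, most regions of each set would lie on the side they had with CpG or polyI:C alone, and the lowest share was 80.2%. The 2 MP libraries that helped to choose the regions may be 1 sample. In CL against PL, 86.2% of the CpG regions and 88.4% of the polyI:C regions kept their side, with medians of 0.36 and -0.40. The camera p-values were 4.56e-32 and 3.33e-40, or 3.96e-07 and 2.07e-07 with an estimated correlation. In CT against PT, 3038 CpG regions and 2366 polyI:C regions were called on their own side, and 133 and 152 on the opposite side. The shares that kept their side in CT against PT were 81.8% and 80.2%, with medians of 0.47 and -0.45. Leaving out 1 library there gave 75% and 72.9% (PT replicate 1), 85.3% and 86.2% (PT replicate 2), 78.1% and 77.1% (CT replicate 1), and 83.5% and 81.6% (CT replicate 2). In both comparisons 1175 regions were called higher with CpG, as they were for CpG alone, and 1131 with polyI:C. Clec16a was at 2.07 ± 0.32 in CL against PL and 3.22 ± 0.32 in CT against PT, and Etv6 at -1.74 ± 0.31 and -2.33 ± 0.31. The 2 first stimuli may thus still be told apart at these regions after 4 h of a second one, although the cells were not sampled between the stimuli or later.

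The spread of log2 CPM over regions was narrower in stimulated libraries than in MM, with an SD of 1.24 in MM, 1.13 in ML replicate 2, 1.07 in MC replicate 1, 1.08 in PT replicate 2 and 0.98 in PL replicate 1. Library depth could give this, but after thinning to 3141641 reads MM still exceeded the wider of CL and PL by 0.218, with at most 0.046 between replicates. More background reads in stimulated cells could also narrow the spread. Of the 5388 regions with the lowest values in MM (10% of all) 9.17% were higher and 12.7% lower in CL against PL. These regions thus did not all change alike in CL and PL. Both groups were stimulated, so a background rise common to them would cancel in this comparison. Whether background added to the narrower spread was therefore not decided.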
